A study of Mus musculus with 4 samples.

How the data were processed

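The samples were 2 of hematopoietic stem cells (HSC, CD34-negative KSL cells) and 2 of multipotent progenitors (MPP, CD34-positive KSL cells), purified by cell sorting from C57BL/6 mice, per the labels. Total RNA was isolated with the ISOGEN reagent and biotinylated cRNA was prepared from RNA equivalent to 3000 cells by 2 cycles of amplification, per the labels' protocols. Repeated amplification of small amounts of RNA favours the 3' ends of transcripts and can blur low signals. The labels name biological replicates without saying whether they came from separate animals, so p-values measure the spread between these samples.

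The values used were the deposited probe set intensity values on a linear scale, in arbitrary units. The software that made them is not given in the sources used here. The mean without the lowest and highest 2% of values was about 100.0 on every array, as the deposited values show, so each array had been scaled to one level. The table held no detection calls, so none were used here. Of 45101 probe sets, the 64 controls were left out. Gene names came from the array's platform annotation, updated through gene identifiers to a RefSeq table of assembly GRCm38.p6, from which no coordinates were used. Of the remaining probe sets, 34945 had 1 gene symbol, 932 several and 9160 none, and 34741 of those with 1 symbol matched the RefSeq table. Only probe sets with 1 symbol named a gene.

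Intensities were analysed as log2(intensity + 6.01), the pseudocount being 0.25 of the median of all values. The log2 medians of the arrays lay within 0.339 of each other, under the limit of 0.5 set for counting the table as normalized, so no further normalization was applied. Probe sets in the lowest 40% of mean level were left out, which left 27022 probe sets and 12382 genes. HSC were compared with MPP in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend on mean level, 2-sided, without covariates, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested at a threshold of 0.05. A gene was represented by its tested probe set with the highest mean. The fit had 2 residual and 8.48 prior degrees of freedom, so the spread was largely borrowed across probe sets.

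The settings above, the rule for named genes, all alternatives and 29 gene lists with 657 members were fixed before the data were examined, and 528 members were tested. Of the listed genes, 20 were in more than 1 list. Lists with at least 3 tested members (27 lists) were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Camera called 13 lists (7 upward, 6 downward). With an estimated correlation it called none, and the lowest adjusted p was 0.253. That form rests on the 2 residual degrees of freedom, so it had little power to call a list whatever the correlation. Oxidative phosphorylation went from camera adjusted p = 8.52e-07 to 0.253 although its estimated correlation was -0.023. For mitosis the estimate was 0.677, far above the preset 0.01. It was 0.435 for the interferon response, 0.308 for erythroid, 0.241 for DNA replication and 0.204 for megakaryocyte genes. The myeloid, homeobox, lymphoid and TGF-beta lists had 0.178, 0.139, 0.111 and 0.088. Correlation between genes therefore stays a limit for all of these lists. fry, which asks only whether a list's own genes move one way, called 16. These were the lists that camera called except the interferon response, and besides them the cell cycle inhibitors, glycolysis and glucose uptake, adhesion and integrins, and macrophage and dendritic markers, all upward. In the main setting, the only one given to fry, the median tested probe set was 0.11 higher in HSC on the log2 scale. Upward calls by fry alone can hold that offset. The sort antigens (2 tested) and sex-linked genes (1 tested) were too few for a list test.

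The named genes followed that rule. It took the 10 genes with the largest log2 difference in each direction among representative probe sets with adjusted p under 0.05 whose HSC values lay on one side of both MPP values, without expressed-sequence, clone or predicted names. It also took the sort antigens, up to 4 members of each list (of those that passed, the 2 with the smallest p per direction, and where none passed, the 2 with the smallest p), and Flt3, Slamf1, Cd48 and Procr. A further sort antigen and some other list members had no named probe set in the annotation used here and are not reported here. Where a gene was at or under the floor on both arrays of a group, its change is given as at least N-fold. The floor was each array's highest signal among 27 probe sets for Bacillus subtilis transcripts, 16.9 and 16.7 on the HSC arrays and 14.9 and 13.6 on the MPP arrays. The labels used here do not say whether any of these transcripts were added to the RNA, in which case the floor holds more than background, but each array's floor lay under its median signal (26.1, 26.9, 22.0 and 21.3). The bound is the ratio of the geometric means of the groups with values under the floor raised to it. This rule was chosen after seeing the data. The test of globin-bearing cells given among the observations was also changed after values were seen. Its first form took the median log2 difference of 8 erythroblast transcripts, which was 0.16. The spread, the SD over genes divided by the square root of their number, was 0.23. These 8 transcripts held none of the called erythroid genes. The globin among them, on a probe set naming Hba-a1 alone, read 13.7 and 2.33 units on the HSC arrays, below the floor. That form therefore decided nothing. The share of probe sets above the floor was 59.3% to 61.4% per array.

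The comparison was tested on simulated data for HSC against MPP over 27022 probe sets. At a log2 change of 1, 12 of 98 changed probe sets were recovered (12.2%), and at 2, 74 of 96 (77.1%), with 12 false calls. Far fewer probe sets were changed than the 2868 called in the data. The adjusted threshold was therefore stricter, and the recovered shares are not those of the real comparison. With no change there were 0 calls and 0 lists. The simulated noise was drawn from the fitted spread and independently between genes, so this could not test the effect of correlated genes. The alternatives were quantile normalization, equal array medians, no filter or a filter of the lowest 60%, other pseudocounts and other prior variances. Further ones were the replicate number as a block, the mean of all probe sets of a gene, and other thresholds. Probe sets whose names end in _x_at, _s_at or _a_at were left out in another. Finally, each array was left out in turn. In the last case the lone array of a group is assumed to vary like the other group's.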

Results

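Gene expression was compared between 2 neighbouring steps of mouse blood formation, the hematopoietic stem cell (HSC) and the multipotent progenitor (MPP) into which it matures. Both populations were sorted from the KSL fraction of C57BL/6 mice, a gate on c-Kit, lineage markers and a further surface antigen that holds the earliest blood cells. HSC lacked the surface protein CD34 and MPP carried it. Each group held 2 samples named as biological replicates. RNA equivalent to 3000 cells per sample was amplified, labelled and hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, which reads a transcript as the signal intensity of a probe set, in arbitrary units. Median intensities were 26.1 and 26.9 on the HSC arrays and 22.0 and 21.3 on the MPP arrays. Across the 27022 probe sets tested, Pearson's r was 0.949 between the HSC arrays, 0.966 between the MPP arrays and 0.903 to 0.916 between arrays of different groups. Probe sets are not independent replicates, and 4 arrays limit the precision of every value below. HSC replicate 2 differed from the other arrays in its control signals: its 3' to 5' signal ratio for actin was 9.42, against 4.99 to 5.26 elsewhere.

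The first comparison checked the sort at the RNA level and asked how the classical surface markers differed between the groups. Cd34 fell in HSC, with 352 ± 165 units (SD, n = 2) against 2135 ± 237 (SD, n = 2) in MPP, a log2 difference of -2.66 (SE 0.27, limma adjusted p = 1.82e-04). Slamf1, a signalling receptor used to isolate HSC, rose from 33.8 ± 5.19 to 383 ± 23.8 (SD, n = 2 each). Procr, the endothelial protein C receptor, rose from 111 ± 4.86 to 573 ± 63.1 (SD, n = 2 each). Flt3, a cytokine receptor of early lymphoid and myeloid progenitors, fell to 118 ± 68.2 from 1319 ± 210 (SD, n = 2 each). Cd48 fell to 21.4 ± 15.5 from 1099 ± 38.5 (SD, n = 2 each), and only 1 of the 2 HSC arrays measured it above the floor, the signal that bacterial control probe sets reached. The log2 differences were 3.29, 2.31, -3.53 and -5.46, with adjusted p between 8.26e-06 and 9.36e-05. Kit, the receptor in the sort gate of both groups, was 1.57-fold higher in HSC (log2 difference 0.65, SE 0.17, adjusted p = 0.0328). It was called in 7 of 13 alternatives, and lost its call with no filter on dim probe sets and without the trend in the prior variance. Kit's call ended without HSC replicate 1, MPP replicate 1 or MPP replicate 2 (log2 differences 0.48, 0.62 and 0.67, adjusted p = 0.0601, 0.220 and 0.182) and with equal array medians (0.41, adjusted p = 0.150).

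**Figure D1:**
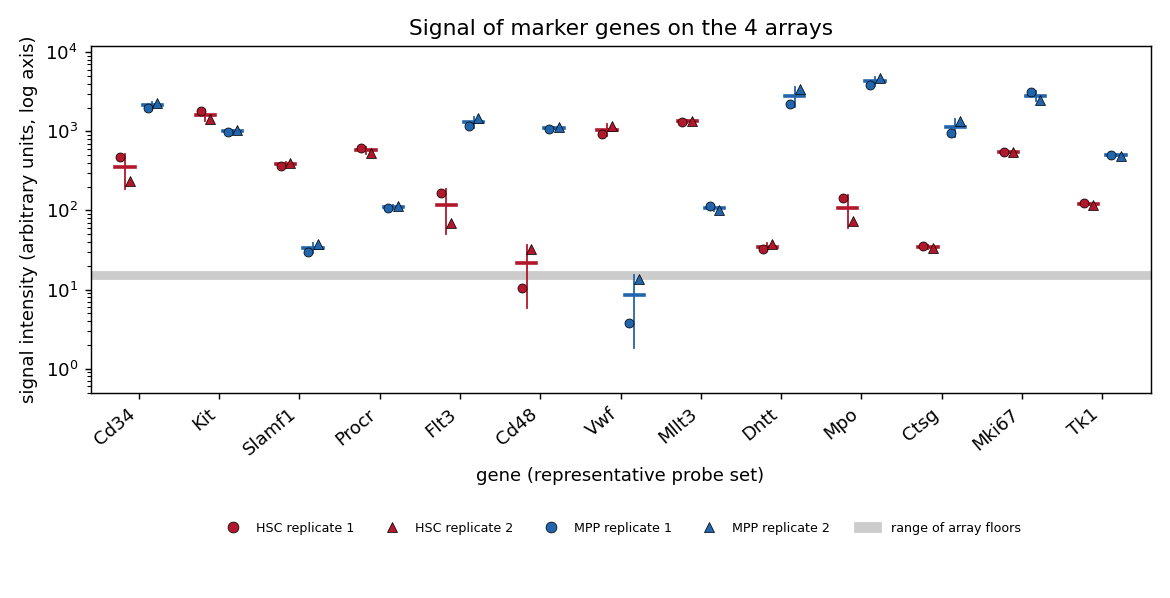
Signal intensity (arbitrary units, log axis) of 13 named genes on the 4 arrays, with HSC in red and MPP in blue, circles for replicate 1 and triangles for replicate 2. Horizontal bars are group means, vertical lines 1 SD (n = 2), and the grey band spans the floors of the arrays, 13.6 to 16.9. Vwf lay below the band on both MPP arrays and at 920 and 1183 on the HSC arrays.

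The main comparison asked which transcripts separated the groups. The largest rise was that of Vwf, von Willebrand factor, from below the floor on both MPP arrays to 1052 ± 186 units in HSC (SD, n = 2), at least 73.2-fold. Car1, a carbonic anhydrase of red cells, was 48.4-fold higher, Sult1a1, a sulfotransferase, 36.0-fold, Clca3a1 15.7-fold, Aldh1a1, which makes retinoic acid, 15.2-fold, and Ndn, the imprinted gene of necdin, 14.2-fold. Gda, guanine deaminase, was higher by a log2 difference of 4.33. Nbea was at least 18.5-fold higher, the growth factor gene Pdgfc at least 13.6-fold and Ermap, an erythroid membrane protein, at least 11.2-fold. In the other direction, Dntt, the terminal transferase of lymphoid progenitors, fell 67.7-fold, from 2826 ± 823 to 35.0 ± 3.30 units (SD, n = 2 each). Cd48 was 44.0-fold lower, Mpo, myeloperoxidase, 38.9-fold, Ctsg, cathepsin G, 28.0-fold, Cd52 26.5-fold, Bex6 24.0-fold, Ighm, the immunoglobulin mu heavy chain, 22.0-fold, and the chemokine gene Ccl3 16.3-fold. Mpeg1 was at least 14.5-fold lower and Cd244a, a receptor that binds Cd48, at least 13.3-fold. These 20 genes had adjusted p between 1.28e-06 and 5.16e-04. Of 5 tested Ighm probe sets, 4 were lower in HSC, and 2 of these were called. Folds are on the log2(intensity + pseudocount) scale, which understates the change of dim genes, and for Car1, Sult1a1, Clca3a1, Cd48, Bex6, Ighm and Ccl3 only 1 of the 2 arrays of the dimmer group measured the gene above the floor.

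In all, 1611 probe sets rose and 1257 fell in HSC at a Benjamini-Hochberg adjusted p under 0.05, or 955 and 731 genes by their representative probe sets. With the array medians made equal, the split became 1020 higher and 2379 lower. The median tested probe set was 0.11 higher in HSC on the log2 scale with values as deposited. That median was -0.01 after quantile normalization and -0.13 with equal medians. As deposited, the shift over all probe sets varied with mean level. Its median was 0.23 in decile 5 of mean level, 0.02 in decile 9 and -0.08 in decile 10, the brightest. Small differences are to be read against the shift at their own level. Without MPP replicate 1 the counts were 1100 higher and 623 lower, without MPP replicate 2 they were 1026 and 568, and without HSC replicate 1 they were 2011 and 1908. Of 860 called genes with several tested probe sets, 707 had every probe set on one side of 0. Tubb4b and Eprs, named because of this result, had probe sets called in both directions.

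**Figure D2:**
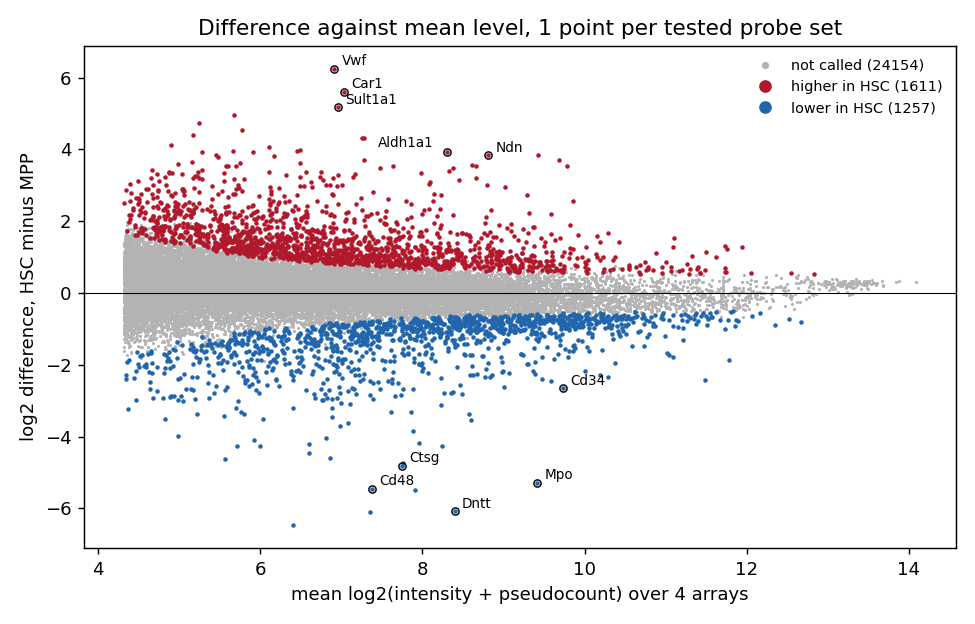
Log2 difference (HSC minus MPP) of each of the 27022 tested probe sets against its mean log2(intensity + pseudocount) over the 4 arrays. Red points are the 1611 called higher in HSC, blue points the 1257 called lower, grey points were not called, and open circles mark 10 named genes, from Vwf, below the floor on both MPP arrays, to Dntt at -6.08.

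Genes known as HSC markers rose together. Of 19 tested members of that list, 17 rose, 1 fell and 1 was not called (18 rose and 1 fell adjusted over the list alone). The median log2 difference was 2.31 (camera adjusted p = 1.82e-17, but adjusted p = 0.253 with an estimated correlation). Mllt3, a chromatin reader, rose from 107 ± 9.39 to 1333 ± 46.3 units (SD, n = 2 each), a log2 difference of 3.56 (SE 0.18), and Ndn had one of 3.83 (SE 0.18). Vldlr, a lipoprotein receptor, fell by 2.67 on the log2 scale (SE 0.31, adjusted p = 4.13e-04). Hlf, named as the member without a call, was at 0.70 (adjusted p = 0.0518).

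Among homeobox genes and their cofactors, 9 of 13 rose and none fell (11 and none adjusted over the list alone), with a median of 1.39 (camera adjusted p = 5.26e-07, but adjusted p = 0.256 with an estimated correlation). Hoxb3 was 4.09-fold higher (SE 0.23 on the log2 scale, adjusted p = 3.51e-04) and Hoxb5 at least 5.40-fold. Hoxa2, Hoxa3, Pbx2 and Hoxa9, named as the 4 without a call, lay between 0.09 and 1.28. Of 20 ABC transporters, membrane pumps that include the dye efflux pump Abcg2, 8 rose and none fell, over all genes and adjusted over the list alone. Their median was only 0.28 (camera adjusted p = 0.00753, but adjusted p = 0.256 with an estimated correlation, and 0.0556 with the mean of all probe sets of a gene). It was 0.52 without HSC replicate 1 and 0.04 with equal array medians. Abcg3, above the floor on 1 of the 2 MPP arrays, was 10.4-fold and Abcg2 2.47-fold higher. In the TGF-beta and BMP pathway 7 of 26 rose and none fell (9 and 1 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.0127, but adjusted p = 0.412 with an estimated correlation). The co-receptor genes Tgfbr3 and Eng were 8.80-fold and 2.65-fold higher. Without MPP replicate 1 the pathway's median was 0.42 with no call (adjusted p = 0.0596) and 3 members rose. Without MPP replicate 2, or with equal array medians, 4 rose. The median was 0.38 without HSC replicate 2, 0.36 with equal array medians and 0.30 without probe sets whose names end in _x_at, _s_at or _a_at.

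**Figure D3:**
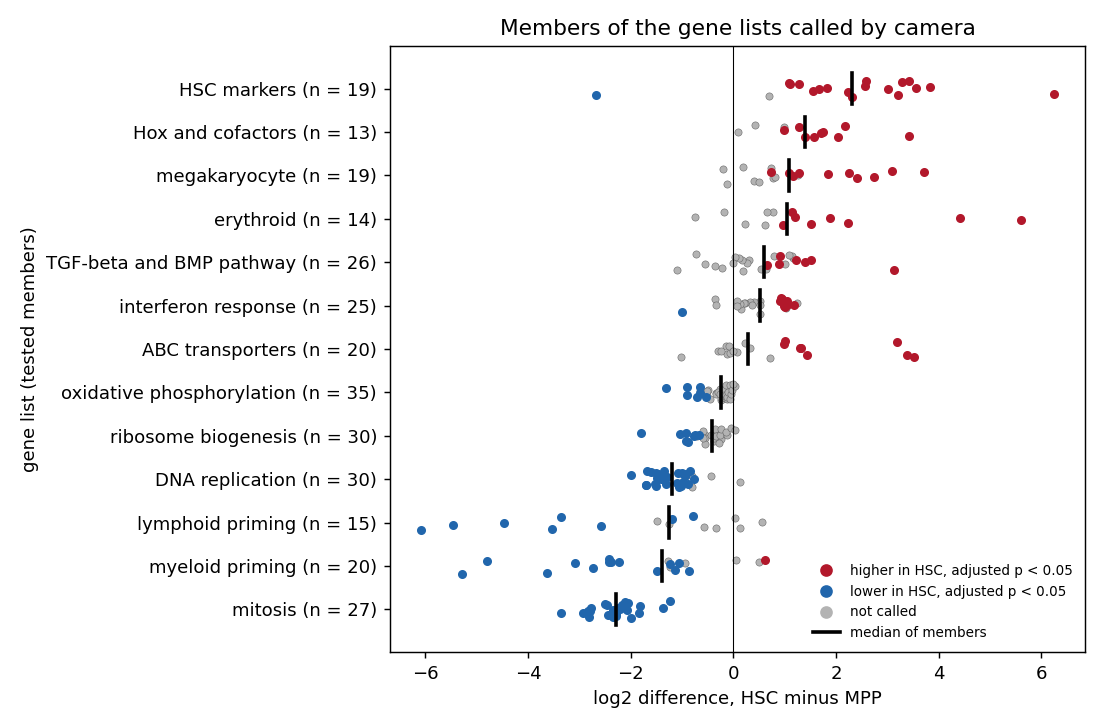
Log2 difference (HSC minus MPP) of the tested members of the 13 gene lists called by camera, 1 point per gene. Red and blue points passed adjusted p < 0.05 upward and downward, grey points did not, and black bars are medians, from 2.31 for HSC markers to -2.29 for mitosis.

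Lymphoid and myeloid genes were lower in HSC. Of 15 lymphoid genes, 8 fell and none rose (11 and 1 adjusted over the list alone). The median log2 difference was -1.25, or -0.95 with members at the floor set to their bound (camera adjusted p = 3.93e-09, but adjusted p = 0.253 with an estimated correlation). Besides Dntt, the genome organiser Satb1 was 10.3-fold lower (SE 0.19 on the log2 scale, adjusted p = 5.77e-06). Of 20 myeloid genes, 14 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.38 (camera adjusted p = 7.69e-14, but adjusted p = 0.253 with an estimated correlation). The neutrophil granule genes Mpo and Ctsg led, with 109 ± 49.5 against 4263 ± 559 units and 34.5 ± 1.80 against 1146 ± 290 (SD, n = 2 each). Lyz2, which encodes lysozyme, was the member that rose (1.54-fold, adjusted p = 0.0320). Its call ended without MPP replicate 1 or 2 (log2 differences 0.64 and 0.59, adjusted p = 0.188 and 0.245) and with equal array medians (0.39, adjusted p = 0.152). Without MPP replicate 2, 5 lymphoid genes fell. The lymphoid median was -0.78 with no filter on dim probe sets or a pseudocount at the median of all values, and -2.28 with the lowest 60% left out.

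Genes of cell division were lower in HSC. All 27 tested mitosis genes fell, over all genes and adjusted over the list alone, by a median log2 difference of -2.29 (camera adjusted p = 5.63e-34, but adjusted p = 0.256 with an estimated correlation). The proliferation marker Mki67 fell to 551 ± 6.57 from 2824 ± 429 units and topoisomerase Top2a to 526 ± 55.9 from 2587 ± 250 (SD, n = 2 each). Of 30 DNA replication genes, 26 fell and none rose (28 and none adjusted over the list alone), with a median of -1.20 (camera adjusted p = 8.57e-24, but adjusted p = 0.253 with an estimated correlation). Thymidine kinase Tk1 was 3.98-fold lower and the flap nuclease Fen1 2.80-fold. Rfc3, Tyms, Ccne1 and Chaf1b, named as the 4 without a call, lay between -0.80 and 0.13.

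Cell cycle inhibitors moved in both directions, and as a list were not called by camera (adjusted p = 0.148) but were called upward by fry (adjusted p = 0.0275). Of 21, 5 rose and 3 fell (8 and 4 adjusted over the list alone). Cdkn1c, which inhibits cyclin-dependent kinases, rose from 26.4 ± 5.63 to 248 ± 42.8 units and Txnip from 696 ± 62.3 to 2248 ± 323 (SD, n = 2 each). Rbl1 fell by 1.51 and Cdkn1a by 2.20 on the log2 scale, with Cdkn1a above the floor on 1 of the 2 HSC arrays. Without MPP replicate 1, 3 rose and 2 fell.

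Small downward shifts were measured for 2 growth-related lists. Of 35 oxidative phosphorylation genes, 7 fell and none rose (11 and none adjusted over the list alone), with a median of -0.25 (camera adjusted p = 8.52e-07, but adjusted p = 0.253 with an estimated correlation). Ndufa4 was 2.50-fold and cytochrome c (Cycs) 1.88-fold lower. Of 30 ribosome biogenesis genes, 8 fell and none rose (12 and none adjusted over the list alone), with a median of -0.41 (camera adjusted p = 1.44e-08, but adjusted p = 0.253 with an estimated correlation). Nop56 was 2.04-fold and Dkc1 1.90-fold lower. Few of these single-gene calls held without either MPP array, but the spread then came from the HSC arrays alone. Those lay further apart (SD of the log2 difference 0.566, against 0.491 between the MPP arrays). A lost call there need not mean a changed difference. Cycs lost its call without either MPP array (log2 differences -0.93 and -0.89, adjusted p = 0.0631 and 0.0804), and Nop56 and Dkc1 without MPP replicate 2 (-0.91 and -0.76, adjusted p = 0.0503 and 0.127). With equal array medians 14 and 15 members fell, with medians of -0.48 and -0.64, and after quantile normalization 4 and 7, with medians of -0.16 and -0.41.

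Erythroid and megakaryocyte genes were higher in HSC. Of 14 erythroid genes, 8 rose and none fell, over all genes and adjusted over the list alone, with a median of 1.05 (camera adjusted p = 6.25e-06, but adjusted p = 0.377 with an estimated correlation). Car1 rose from 13.3 ± 6.24 to 944 ± 384 units and Ermap from below the floor to 164 ± 54.3 (SD, n = 2 each). On a probe set assigned jointly to 2 alpha-globin genes, HSC replicate 1 read 1026 units, HSC replicate 2 82.9 and the MPP arrays 17.99 and 29.8. This probe set and a second one of the same genes were called higher in HSC. Their log2 differences were 3.37 and 3.11 (limma adjusted p = 0.0254 and 0.0336). Gata1, Tfrc, Epor, Add2, Rhd and Icam4, the 6 without a call, lay between -0.75 and 0.78. Gata1, at -0.75, read 6.39 units on HSC replicate 1, below the floor, and 104 on HSC replicate 2, against 51.1 and 61.8 on the MPP arrays. Of 19 megakaryocyte genes, 10 rose and none fell (14 and none adjusted over the list alone), with a median of 1.08 (camera adjusted p = 2.72e-07, but adjusted p = 0.306 with an estimated correlation). Mmrn1, multimerin, rose from 238 ± 0.964 to 1615 ± 88.3 units and Cavin2 from 37.1 ± 7.15 to 554 ± 25.1 (SD, n = 2 each). Without MPP replicate 2, 6 megakaryocyte genes rose. Without HSC replicate 1, 8 erythroid and 9 megakaryocyte genes rose.

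**Figure D4:**
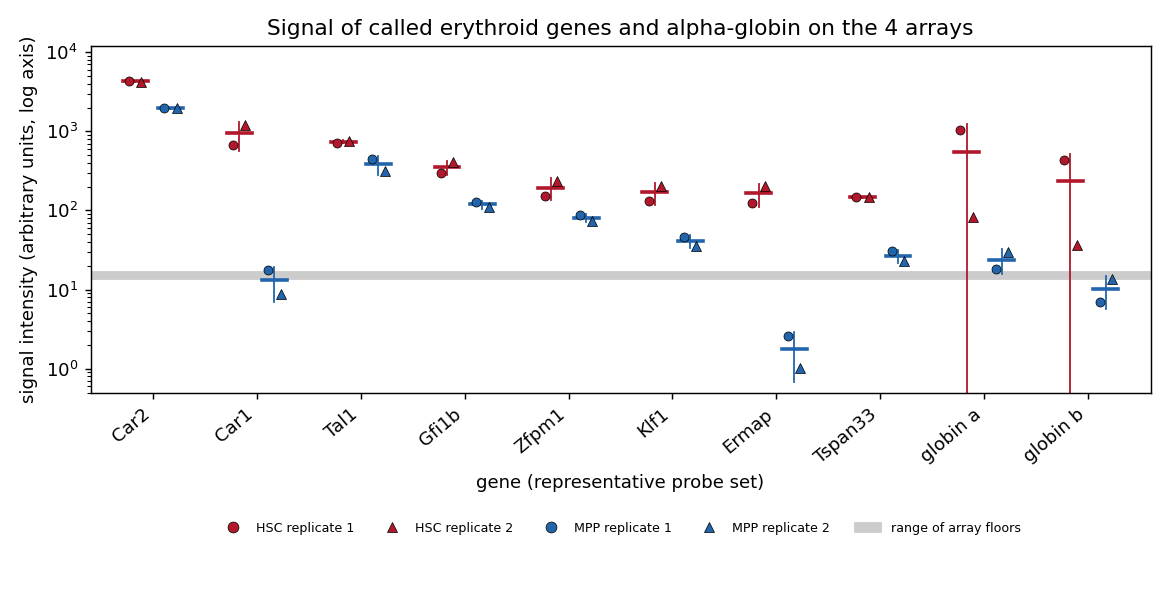
Signal intensity (arbitrary units, log axis) of the 8 called erythroid genes and of 2 probe sets assigned jointly to alpha-globin genes (globin a and b) on the 4 arrays. Symbols, bars, lines and band are as for the marker genes, and SD lines end at the axis where they reach below it. Car1 was at 672 and 1215 on HSC replicates 1 and 2, while globin a was at 1026 and 82.9.

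Of 25 interferon response genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.00265, but adjusted p = 0.626 with an estimated correlation). It was the list called by camera that fry did not call (adjusted p = 0.182). Ifitm3 was 2.06-fold and Gbp2 1.99-fold higher, and the proteasome subunit gene Psmb8 was 2.01-fold lower. Without MPP replicate 1 the median was 0.23 with no call (adjusted p = 0.215), 1 member rose, and Ifitm3 was at 0.88 (adjusted p = 0.0550). With equal array medians 4 rose and the median was 0.28. Psmb8 lost its call without MPP replicate 1 or 2 (adjusted p = 0.0604 and 0.0580).

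The other functional lists were not called by camera. Of 25 cytokine receptors, 4 rose and 7 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.113). Tek, the angiopoietin receptor, rose 3.17-fold and Bmpr1a 2.85-fold, and Il1r1 fell 11.4-fold, like Flt3, with Il1r1 above the floor on 1 of the 2 HSC arrays. This list was called downward without HSC replicate 1, HSC replicate 2 or MPP replicate 1 (medians -0.01, -0.36 and -0.25, adjusted p = 0.0486, 0.0459 and 0.0278), with 2, 4 and 1 members higher. Without MPP replicate 2, or with equal array medians, 2 rose. Bmpr1a lost its call without HSC replicate 1 or MPP replicate 1 (log2 differences 1.31 and 1.35, adjusted p = 0.0556 and 0.0678). Of 26 adhesion genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.185, but fry adjusted p = 0.0320 upward). The junction genes Jam3 and Esam were 6.12-fold and 2.93-fold higher, and Itgal and Cd44 were 7.97-fold and 1.91-fold lower, with Jam3 and Itgal above the floor on only 1 of the 2 arrays of the dimmer group. Without MPP replicate 2, 5 rose and 1 fell, and Cd44 was at -0.88 with no call (adjusted p = 0.0590).

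Of 24 Polycomb genes, 1 rose and 5 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.160). Cbx7 was 2.45-fold higher, and the methyltransferase gene Ezh2 3.09-fold and Mtf2 1.69-fold lower, followed by Suz12, Pcgf5 and Eed, named to complete the 5. Of the tested probe sets of Mtf2, Suz12 and Eed, 4 of 5, 3 of 5 and 1 of 2 were lower. Only 1 of each gene was called lower. The members that rose numbered 4 without HSC replicate 1, 2 without MPP replicate 1 and none without MPP replicate 2. Without MPP replicate 1 or 2, 1 Polycomb gene fell, Mtf2 lost its call (log2 differences -0.78 and -0.73, adjusted p = 0.0950 and 0.127), and Cbx7 lost its call without MPP replicate 2 (1.08, adjusted p = 0.101). Of 26 DNA and chromatin modifiers, 1 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.933). Smarca2 was 2.49-fold higher, and the DNA methyltransferase genes Dnmt1 and Dnmt3b were 2.12-fold and 1.53-fold lower. Dnmt3b lost its call without MPP replicate 1 or 2 (-0.65 and -0.59, adjusted p = 0.181 and 0.247) and after quantile normalization (-0.47, adjusted p = 0.0601), which left 1 member lower in each case, and without MPP replicate 2 there were 2 higher.

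In glycolysis and glucose uptake 4 of 20 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.933, but fry adjusted p = 0.0424 upward). By sign, 10 of the 20 were higher in HSC. The median was 0.06, and from -0.17 to 0.14 over equal array medians and quantile normalization. The fry call therefore does not show a shared rise. The glucose transporter gene Slc2a3 was 2.70-fold and the hypoxia-responsive Epas1 3.77-fold higher, followed by Pdk4 and Ldhb, named to complete the 4. Pgam1 was 2.36-fold and Tpi1 1.69-fold lower, and Tpi1 lost its call without MPP replicate 1 or 2 (log2 differences -0.68 and -0.84, adjusted p = 0.177 and 0.0794), leaving 1 lower. The members that fell numbered 4 without HSC replicate 2 and 5 with equal array medians. Of 13 antigen presentation genes, 2 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.208). The class II genes H2-Aa and H2-Eb1 were 4.90-fold and 2.50-fold higher, while H2-DMa and Tap2 were 2.00-fold and 1.98-fold lower. H2-DMa lost its call without MPP replicate 2 (-0.89, adjusted p = 0.0766) and Tap2 without MPP replicate 1 (-0.83, adjusted p = 0.138), and 1 member fell in each case.

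Of 27 immediate early and stress genes, 2 rose and 1 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.369). Egr2 and Egr1 were 2.80-fold and 2.48-fold higher, with Egr2 above the floor on 1 of the 2 MPP arrays, and the heat shock gene Hspa1b was 2.94-fold lower. None of the 3 calls held in every setting: Egr1 was called in 8 of 14 alternatives, Egr2 in 8 of 13 and Hspa1b in 7 of 13. Some of the alternatives that ended a call follow. Egr1 was at 0.96 without HSC replicate 2, 0.67 without MPP replicate 1 and 1.08 with equal medians (adjusted p = 0.0847, 0.247 and 0.0746). Egr2 had no call without HSC replicate 1, HSC replicate 2 or MPP replicate 2 or after quantile normalization (1.49, 1.48, 1.31 and 1.27, adjusted p = 0.0588, 0.0691, 0.127 and 0.0537). Hspa1b had none without HSC replicate 1 or MPP replicate 2 (-0.80 and -1.15, adjusted p = 0.0950 and 0.187). The list's median was -0.43 without HSC replicate 2 and -0.44 without MPP replicate 1. It was 0.27 without HSC replicate 1 and 0.33 without MPP replicate 2. These genes were lower on replicate 1 in both groups, with median log2 differences from replicate 2 of -0.70 in HSC and -0.81 in MPP. Leaving out 1 array unbalances the replicates, so these medians do not show a difference between the groups. Without MPP replicate 2, 4 rose and none fell, and with equal array medians 1 rose and 4 fell.

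Markers of other cell types were mostly dim and were not called as lists by camera. None of 9 B cell, 3 T and NK cell and 4 mature granulocyte markers above the filter on dim probe sets passed, over all genes or adjusted over the list alone (camera adjusted p = 0.796, 0.933 and 0.933). The lowest p values belonged to Cr2 and Cd22 (log2 differences 1.00 and 0.61), Cd8a and Klrd1 (0.86 and -0.63), and Mmp9 and Fcnb (0.77 and 0.51). Of 15 macrophage and dendritic markers, the iron exporter gene Slc40a1 rose 2.76-fold and Csf1r, also on the myeloid list, fell 8.52-fold (camera adjusted p = 0.540, but fry adjusted p = 0.0275 upward). With equal array medians or quantile normalization 2 fell. Of 7 mast cell and basophil markers, Il4 rose at least 4.66-fold and Mitf 2.00-fold, and Cpa3 fell 1.94-fold (camera adjusted p = 0.986). The list's median was -0.28, from -0.62 to 0.88 over the alternatives, and its mean was 0.28. Of 12 stromal and endothelial markers, Col1a2 rose 3.98-fold and Kdr, above the floor on 1 of the 2 MPP arrays, 3.69-fold, and Pdgfrb fell 4.49-fold (camera adjusted p = 0.659). The counts of these 3 lists adjusted over the list alone were the same. Mitf and Cpa3 lost their calls without MPP replicate 2 (log2 differences 0.92 and -0.91, adjusted p = 0.101 and 0.144), Cpa3 also without MPP replicate 1 (adjusted p = 0.0927), and Kdr without HSC replicate 2 or MPP replicate 2 (1.44 and 1.35, adjusted p = 0.0920 and 0.0827). Xist, the transcript of the inactive X chromosome, read 5637 ± 377 units in HSC and 6335 ± 162 in MPP (SD, n = 2 each), a difference that did not pass (adjusted p = 0.513), and no Y-linked gene of the list was among the tested genes.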

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

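All tests in this part, and the limit of 1.5 times, were chosen after the result was seen. The control probe sets, which the comparison of HSC with MPP did not use, set HSC replicate 2 apart. Its 18 hybridisation controls, bacterial and phage transcripts added in fixed amounts, averaged 1.81-fold over the other 3 arrays, against 0.741 to 0.873 for the others. The 3' to 5' signal ratio was 9.42 for actin, against 4.99 to 5.26, and 5.81 for Gapdh, against 4.88 to 5.15. The signal of the 5' part of 18S ribosomal RNA was 10696 units, against 3382 to 5139. Each of these except the Gapdh ratio was more than 1.5 times that of any other array.

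Of 2 technical explanations, less labelled mouse RNA on the array before scaling predicts that the added controls all rise, and 18 of 18 were highest on HSC replicate 2. Shorter cDNA predicts that both 3' to 5' ratios rise, and 2 of 2 did. These are the controls that set the array apart, so the tests decide for neither, and the 2 explanations cannot be told apart. No biological explanation was tested, since the pattern lies in 1 array. Without HSC replicate 2 the comparison called 1521 probe sets higher and 1541 lower in HSC.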

How the results depend on the processing

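All alternatives in this part were planned. No call shared with another setting changed direction, and no named gene or list reversed its call. Of 91 named genes, 65 were on the same side of the threshold in every alternative, and 80 of 1235 gene-by-alternative values lost their call, 24 of them without a trend in the prior variance. The counts of probe sets higher and lower in HSC (1611 and 1257) became 1020 and 2379 with equal array medians, 917 and 780 with no filter on dim probe sets, and 633 and 374 without the trend. At adjusted p under 0.10, 2459 were higher, and at adjusted p under 0.05 with at least a 2-fold difference, 751 were lower. Leaving out one array gave 1026 to 2011 higher and 568 to 1908 lower, with 1 residual degree of freedom. Adding the replicate number as a block gave 2525 and 1833, and the cytokine receptors were then called downward (adjusted p = 0.00263, against 0.00263 to 0.251 over all alternatives). Deviations of same-numbered arrays correlated at 0.027 over all tested probe sets, and with 2 pairs the numbers were not taken to pair the samples. A replicate effect on some genes stays open: in both groups, 21 of 27 immediate early genes were higher on replicate 2 and 24 of 27 mitosis genes on replicate 1, lists singled out after their values were seen. The immediate early list's medians with 1 array left out moved with that difference between replicates. What set the replicates apart, and the cause of the other changes, were not tested. Of the 13 lists called, 0 were called with an estimated correlation, a form with little power at the 2 residual degrees of freedom of the main fit. The ABC transporters (median 0.276) were not called with the mean of all probe sets of a gene (adjusted p = 0.0556, against 4.83e-04 to 0.0556 over all alternatives). With one array left out, the medians of the TGF-beta and BMP pathway ranged from 0.379 to 0.659 (0.416, not called, without MPP replicate 1, with adjusted p from 0.00169 to 0.0596 over all alternatives) and those of the interferon response from 0.227 (not called, without MPP replicate 1) to 0.639 (adjusted p from 8.11e-06 to 0.215). With the preset correlation, the other 10 called lists passed in all 15 alternatives. Signal limits what dim genes can show: only 59.3% to 61.4% of probe sets lay above the floor on each array.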

Other observations

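The genes and all tests in this part were chosen after results were seen. Genes known as imprinted, which are expressed from 1 parental copy in at least some tissues, stood out beyond Ndn and Cdkn1c. The arrays do not tell the parental copies apart. Meg3 read 583 and 775 units on the HSC arrays against 53.0 and 52.2 on the MPP arrays, Grb10 1107 and 975 against 96.2 and 89.3, and Plagl1 88.3 and 85.8 against 2.31 and 4.20, below the floor. Of 24 tested imprinted genes whose values had not been seen when a list of 43 was written, 6 rose (Airn, Igf2, Phlda2, Igf2r, Sgce and Cd81) and 1, Osbpl5, fell. Airn read 145 and 208 units against 27.8 and 22.9 (log2 difference 2.52, limma adjusted p = 3.69e-04), and Igf2 58.5 and 60.7 against 10.3 and 7.03, below the floor.

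Besides Aldh1a1, 5 single genes were picked out because they had passed, and no list of such genes was tested. Except for Aldh1a7, named only as a relative of Aldh1a1, they are linked to retinoic acid. Cyp26b1, which degrades retinoic acid, read 111 and 130 units on the HSC arrays against 5.65 and 2.64 on the MPP arrays, below the floor (limma adjusted p = 1.79e-04). Rarb, a retinoic acid receptor, read 71.4 and 75.3 against 6.48 and 10.2, below the floor (adjusted p = 0.00202), and Aldh1a7 43.0 and 47.7 against 9.76 and 8.60, below the floor (adjusted p = 0.0187). Rdh10, which makes retinaldehyde, was higher by a log2 difference of 0.79 (adjusted p = 0.0476), and Dhrs3, which removes it, was lower by one of -1.32 (adjusted p = 0.0104).

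A shared rise of imprinted genes was tested on the 24 members not seen before. Their median log2 difference was 0.53, and camera gave p = 0.0117 upward (0.00929 after quantile normalization), but p = 0.194 with an estimated correlation. An offset of dim probe sets between the arrays is argued against, since the median lay at percentile 99.83 of 10000 random lists matched on mean level, whose own median was 0.13. A shared rise of imprinted genes in HSC may therefore be followed up as a hypothesis, found and tested on the same arrays. The preset correlation of 0.01 and the random lists took the members as nearly independent genes, which they need not be.

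The rise of erythroid and megakaryocyte genes was weighed against RNA of mature cells in the sort, although the lineage gate would remove many of these. Globin-bearing erythroid cells among the sorted HSC would carry their genes with the globin, which was far higher on HSC replicate 1 (1026 units) than on replicate 2 (82.9). The 8 called erythroid genes instead had a median log2 difference of -0.52 for replicate 1 over replicate 2. Their spread, the SD over genes divided by the square root of their number, was 0.12. A call favours genes alike on the 2 HSC arrays, but all 14 tested erythroid genes had a median of -0.37, with 2 higher on replicate 1. This argues against globin-bearing cells as their source, as far as 1 array each can, and HSC replicate 2 was set apart by its controls. Erythroid precursors that make no globin stay open. An offset between the arrays is argued against too, since the erythroid median was 1.08 after quantile normalization. Megakaryocytes or platelets cannot be told apart from expression by HSC: 10 platelet transcripts had a median of 0.75 (spread 0.23), between the values set for either reading, with Pf4 at 497 and 382 units against 203 and 151.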
